A study of Saccharopolyspora erythraea with 4 samples.

How the data were processed

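The 4 samples were RNA-seq libraries of wild-type S. erythraea NRRL23338, 2 harvested at 10 h and 2 at 50 h, grouped by the growth phase and time in the labels. Per the labels' protocols, cells were kept in an RNA-stabilising solution, RNA was extracted with bead disruption and DNase treatment, ribosomal RNA was removed, and the second cDNA strand was made with dUTP and degraded before amplification, which keeps the strand. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The values are TPM as deposited by the authors, 1 column per sample, and each column sums to 1000000 over 6993 genes. The aligner, the counting tool, its strand setting and the genome build are not given in the sources used here. TPM keeps no record of read depth, so no counting interval could be given for any value, and a gene listed at 0 may be a failed estimate. Reads shared between near-identical genes, such as the copies of IS256 transposases, cannot be assigned from these values.

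Locus tags were matched to a RefSeq gene table of assembly ASM6288v1, used for older tags, symbols, gene order and coding length. Of the 6993 genes 6786 (97.0%) matched and 6643 had an older tag, and 1345 genes were described as hypothetical protein. Of the 23 older tags of the erythromycin cluster 22 were analysed here. The tag without a matched gene lies between SACE_0720 and SACE_0722.

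Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(TPM + 1), two-sided, for genes with a mean of at least 1 TPM over all samples, with Benjamini-Hochberg adjustment over the 6960 tested genes. The added 1 TPM shrinks the fold change of low genes, while differences between the libraries' lowest values can inflate it. The median log2 difference over the tested genes was 1.18. It was 0.08 after each library's lowest decile was subtracted, with a pseudocount of 1. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. In this fit the prior degrees of freedom were infinite, so each gene's spread was taken wholly from the trend and not from its own replicates, and its adjusted p-values are very small. An exact permutation test of 2 against 2 cannot go below a two-sided p of 0.333. The fit on genes with a mean of at least 100 TPM, where the prior had 7.88 degrees of freedom, was added after the data were seen, and standard errors in the text are those of the fit over all genes unless stated. For 163 genes of the rule for named genes that are in both fits, the standard error with the filter at 100 TPM was 1.01 times the other at the median, 2.43 times at the 95th percentile and 15.3 times at most. Gene lists (32, chosen by locus tag or product name) were tested with camera on the same values, with a preset correlation of 0.01 and with an estimated one, for lists of at least 4 tested genes, adjusted over the lists. Camera compares a list with all other genes, so its direction is relative to them and is not the sign of the list's own change. With the preset correlation 13 lists passed, and with the estimated correlation 0 passed. Runs of at least 6 neighbouring genes called 1 way were counted against 10000 shuffles of the gene order. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.

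The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule allowed the erythromycin genes and regulators, the 12 largest changes per direction with a group mean of at least 50 TPM, no overlap and a described product, up to 4 called genes per list by size of change (or the 2 most abundant where none was called), the 5 most abundant genes at each time, and up to 2 genes per run. It took 222 genes, of which the text names a part, selected after their values and their stability were seen. An earlier, smaller part had left out genes that lost their call in an alternative, and several of these are now named with the loss stated. A further 4 genes with values, L30, and some list members named without expression values, were chosen after their values were seen, and the text says so. Stability is given in the closing section over all of the 222 and these 4, not over the named part, and L30 and members named without expression values are not in that count. Product-name patterns also caught members of other function: 21 of 139 in the TetR list, 9 of 44 in cell division, 7 of 37 in chaperones, 6 of 21 in phosphate, 3 of 15 in translation factors, 2 of 20 in the tricarboxylic acid cycle, 2 of 29 in other polyketide, peptide and terpene synthases and 1 each in nitrogen assimilation, cobalamin synthesis and branched-chain degradation. The lists were kept as fixed, and a version without those members was added.

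The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a mean of at least 10 TPM, quantile normalization, median-ratio scaling, no intensity trend, the replicate number as a block, no minimum difference and leaving out each library in turn. In the last, the lone library of its time is assumed to vary like the others. Alternatives added after the data were seen were the filter at 100 TPM, crossed replicate numbers, and subtraction of each library's lowest decile from every gene with pseudocounts of 1 and 50. The procedure was tested on simulated 50 h against 10 h data with 6960 genes, 211 of them changed. It recovered 44.9%, 40%, 42% and 87.1% of genes changed by log2 1.5, 2, 3 and 5, and 100% at each size for genes with a mean of at least 100 TPM, though these were only 11, 7, 3 and 20 genes, with 0 in the wrong direction. It called 8 of 6749 unchanged genes, and 0 of 6952 when no gene was changed. Of 200 random lists 4% had a camera p under 0.05 when no gene was changed. The simulated spread followed the trend, so real genes with more spread than the trend are not covered by this test. Genes were simulated independently of each other and without differences between libraries at the low end. The rate for random lists thus does not cover correlated genes. The estimated correlation was 0.57 for ribosomal protein genes and 0.95 for the erythromycin cluster.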

Results

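The data describe the wild-type strain NRRL23338 of Saccharopolyspora erythraea, a filamentous soil actinomycete that makes the macrolide antibiotic erythromycin. Cultures in a modified minimal liquid medium were sampled at 10 h, in early exponential growth, and at 50 h, in stationary phase. RNA freed of ribosomal RNA was sequenced in 2 libraries per time, 4 in all. The series title concerns a higher-producing strain, but all 4 samples analysed here are wild type, so the comparison made is stationary against exponential phase. Expression was given as TPM, a share of all transcripts corrected for gene length, for 6993 genes. Each library summed to 1000000 TPM, a unit that keeps no record of read depth, so the depth of each library is unknown. TPM values below are mean ± SD over 2 libraries (n = 2), given from 10 h to 50 h. Log2 differences are 50 h minus 10 h on the log2(TPM + 1) scale, ± their standard error.

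The makeup of the transcript pool differed between the times. Ribosomal protein genes held 23.7% and 24.3% of all TPM in the 10 h libraries and 4.4% and 3.3% in the 50 h libraries. The 10 most abundant genes of each library held 8.4% and 9.2% at 10 h, against 27.6% and 24.1% at 50 h. Replicates were closer to each other (Pearson correlation across genes of log2 values 0.925 at 10 h and 0.889 at 50 h) than libraries of different times (0.555 to 0.667), where genes are not independent replicates. At the low end the libraries of 1 time also differed. The lowest decile of gene values lay at 11.1 and 0.63 TPM in 10 h replicates 1 and 2, and at 15.8 and 38.3 TPM in 50 h replicates 1 and 2. The number of genes listed at 0 was 59, 239, 53 and 78 in the same order.

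**Figure D1:**
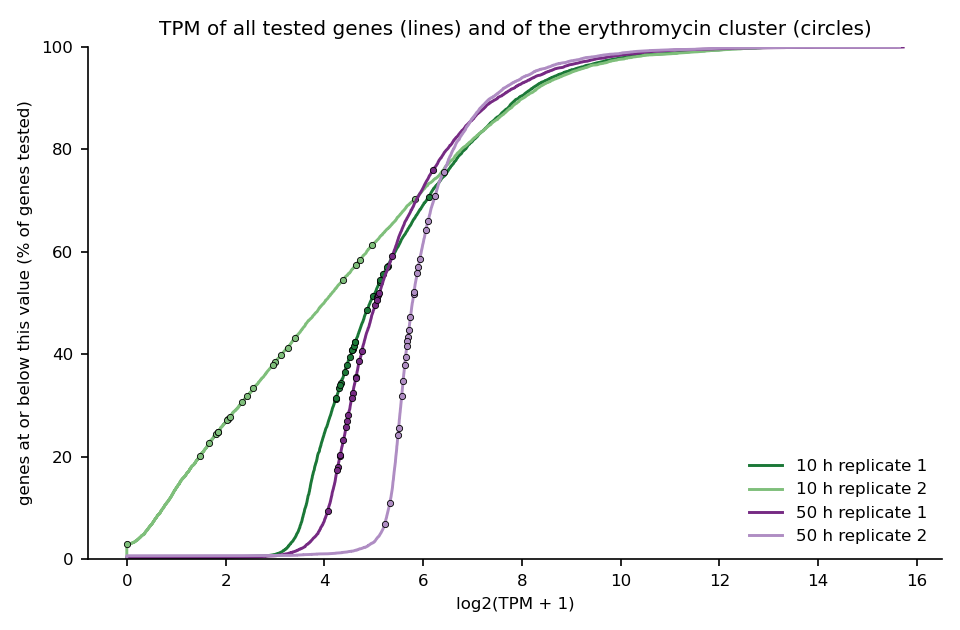
Each line gives, for 1 library, the percentage of the tested genes (vertical axis) at or below a log2(TPM + 1) value (horizontal axis), and circles mark the 22 erythromycin cluster genes on the line of their library. The lowest decile lies at 0.63 TPM in 10 h replicate 2 and at 11.1 to 38.3 TPM in the other libraries, and the cluster genes lie along the low and middle parts of every line.

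Between exponential and stationary phase, many genes of protein synthesis, central carbon metabolism and amino acid and nucleotide synthesis fell, while those of NADH dehydrogenase, some acyl-CoA dehydrogenases, a nitrite reductase subunit and a set of very abundant uncharacterised transcripts rose. The nickel superoxide dismutase gene sodN (SACE_RS30850) fell from 6283 ± 500.1 to 107 ± 4.96 TPM, a log2 difference of -5.86 ± 0.18. A gene for an XRE family transcriptional regulator (SACE_RS09280) rose from 7.20 ± 6.20 to 1923 ± 334 TPM, a log2 difference of 8.11 ± 0.22. Its 10 h values were 11.58 and 2.81 TPM, the first near its library's lowest decile, so the size depends on the low end. The log2 difference was 10.05 and 5.53 after background subtraction with pseudocounts of 1 and 50. In the fit on genes with a mean of at least 100 TPM its standard error was 0.43. Of 6960 genes tested with limma, 1790 were called at an adjusted p under 0.05 and an absolute log2 difference of at least 1, with 789 higher and 1001 lower at 50 h. Without 50 h replicate 1 the number called higher was 488. The median log2 difference over all genes was 1.18 with TPM as deposited, -0.04 after quantile normalization and 0.22 after median-ratio scaling. It was 0.08 after background subtraction with a pseudocount of 1. List medians are also given relative to the value of 1.18. Among the 1578 genes with a mean of at least 100 TPM the median was -0.98. For lists of abundant genes the relative value thus overstates how far they fell beyond genes of like abundance. Median-ratio scaling divides each library by 1 factor. In the 10 h libraries 1 factor did not describe low and abundant genes alike (ratios 6.12 and 0.89), so a call lost under this scaling may come from that limit. The call rests on a spread shared by genes of like abundance, and a fit without that intensity trend called 0 genes. It had 2006 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.059. For single genes the adjusted p given is therefore that of a limma fit on the 1578 genes with a mean of at least 100 TPM, in which each gene's own spread carries weight, unless stated otherwise. In that fit 1096 genes were called, 315 higher and 781 lower.

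Ribosomal protein genes fell at 50 h. L7/L12 (rplL, SACE_RS33080), the stalk protein that recruits elongation factors, fell from 9529.5 ± 706 to 438 ± 39.6 TPM (log2 difference -4.44 ± 0.26, adjusted p = 3.69e-08). L10 (rplJ, SACE_RS33085), which anchors the stalk, fell from 5156 ± 457 to 281 ± 37.2 TPM (log2 difference -4.20 ± 0.20, adjusted p = 3.69e-08). The most abundant transcript at 10 h, S17 (rpsQ, SACE_RS32870), fell from 11597 ± 1648 to 1434 ± 114 TPM, a log2 difference of -3.01 ± 0.37. Of 54 tested ribosomal protein genes 48 were called lower, 1 higher and 5 neither, and 50 were called when adjusted over the list alone (camera adjusted p = 2.61e-26; adjusted p = 0.59 with an estimated correlation). The list median was -2.63, or -3.81 relative to the all-gene median. Among genes with a mean of at least 100 TPM the list median was -2.65, against -0.98 for all genes of that fit. The 1 gene called higher, S14 type Z (SACE_RS32850, chosen after its values were seen), stood at 8066.9 and 0 TPM in 10 h replicates 1 and 2 and at 1288 and 623 TPM in the 50 h libraries. That call came from the value listed at 0, since the log2 difference was -3.17 without 10 h replicate 2 (adjusted p = 2.42e-08) and the adjusted p was 0.305 among genes with a mean of at least 100 TPM. The call lower of L30 (SACE_RS32825, chosen after its values were seen) has the same flaw, with 9067 and 0 TPM at 10 h and 1356 and 0 TPM at 50 h. Its log2 difference of -1.37 became 5.20 without 10 h replicate 1 and 3.83 without 50 h replicate 2, and its adjusted p was 0.746 among genes with a mean of at least 100 TPM. In all, 23 genes were listed at 0 in 1 library and at 100 TPM or more in its replicate, and the 21 of them with a known coding length were all shorter than 300 bases. The rpsQ call was lost without 50 h replicate 1 (log2 difference -3.09, adjusted p = 0.0896) and without 50 h replicate 2 (-2.93, 0.0555).

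Many other translation genes fell with them. Elongation factor Ts (tsf, SACE_RS28950) fell from 2591 ± 309 to 245 ± 25.6 TPM (log2 difference -3.40 ± 0.18, adjusted p = 7.87e-08), and elongation factor G (fusA, SACE_RS32930), which moves the ribosome along the message, fell by 2.66 ± 0.27 on the log2 scale. Another gene of that family, EF-G2 (SACE_RS09840), rose from 10.5 ± 7.68 to 149.6 ± 11.2 TPM (log2 difference 3.89 ± 0.61, adjusted p = 1.61e-09 over all tested genes), a call lost without 50 h replicate 1 (log2 difference 3.81, adjusted p = 0.121). Of 15 translation factors 8 were called lower and 1, EF-G2, higher (camera adjusted p = 0.000172; adjusted p = 0.59 with an estimated correlation). For the list the median log2 difference was -1.95, or -3.13 relative to the all-gene median. The camera adjusted p of that list was 0.0677 after median-ratio scaling. Of 23 aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 15 were called lower and 1 higher (camera adjusted p = 0.000159; adjusted p = 0.59 with an estimated correlation), with a list median of -1.27, or -2.45 relative to the all-gene median. Among genes with a mean of at least 100 TPM that list median was -1.32, against -0.98 for all genes of that fit. Glutamyl-tRNA synthetase (gltX, SACE_RS29510) fell from 507 ± 10.6 to 116 ± 3.63 TPM, and the 1 called higher was tryptophanyl-tRNA synthetase (trpS, SACE_RS04900), with a log2 difference of 2.01 ± 0.28 that was 1.03 after median-ratio scaling (adjusted p = 0.232).

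The respiratory chain split into a part that rose and a part that fell. The flavoprotein subunit of a succinate dehydrogenase or fumarate reductase (SACE_RS05710) rose from 10.4 ± 10.3 to 602 ± 108 TPM (log2 difference 6.10 ± 0.32, adjusted p = 9.32e-06), and its iron-sulfur subunit (SACE_RS05715) rose by a log2 difference of 5.82 ± 0.27. Their standard errors were 0.66 and 0.52 in the fit on genes with a mean of at least 100 TPM. All 14 subunits of the NADH-quinone oxidoreductase on the list were called higher, among them subunit D (SACE_RS33260), from 20.2 ± 9.12 to 269 ± 30.8 TPM (log2 difference 3.74 ± 0.31). The subunit A call (SACE_RS33275) was lost after median-ratio scaling (1.71, adjusted p = 0.0629). A cytochrome c oxidase subunit I gene (ctaD, SACE_RS33970) rose from 12.2 ± 9.03 to 183 ± 9.85 TPM, a log2 difference of 3.99 ± 0.50. Of 27 genes 18 were called higher and 8 lower (camera adjusted p = 0.00534; adjusted p = 0.877 with an estimated correlation). Here the median log2 difference was 3.13, or 1.95 relative to the all-gene median. The 8 called lower were the 4 genes of another succinate dehydrogenase, another ctaD, the subunits II and 4 of cytochrome c oxidase and the iron-sulfur subunit of menaquinol-cytochrome c reductase. Among these, chosen after their values were seen, sdhA (SACE_RS31670) fell from 503 ± 44.0 to 112 ± 3.77 TPM and that ctaD (SACE_RS05785) fell from 924 ± 122 to 171 ± 12.9 TPM. The camera result of the list was not stable, since its direction, which is relative to all other genes, turned to down without 50 h replicate 1. Its camera call was also lost without 50 h replicate 2. The list median itself stayed between 2.75 and 3.75 over the libraries left out. F-type ATP synthase genes fell, with 7 of 8 called lower (camera adjusted p = 6.88e-12; adjusted p = 0.59 with an estimated correlation). For it the median log2 difference was -3.01, or -4.19 relative to the all-gene median. Its subunit C (SACE_RS30190), the membrane ring, fell from 3189 ± 458 to 298 ± 64.6 TPM (log2 difference -3.43 ± 0.19, adjusted p = 1.92e-07).

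**Figure D2:**
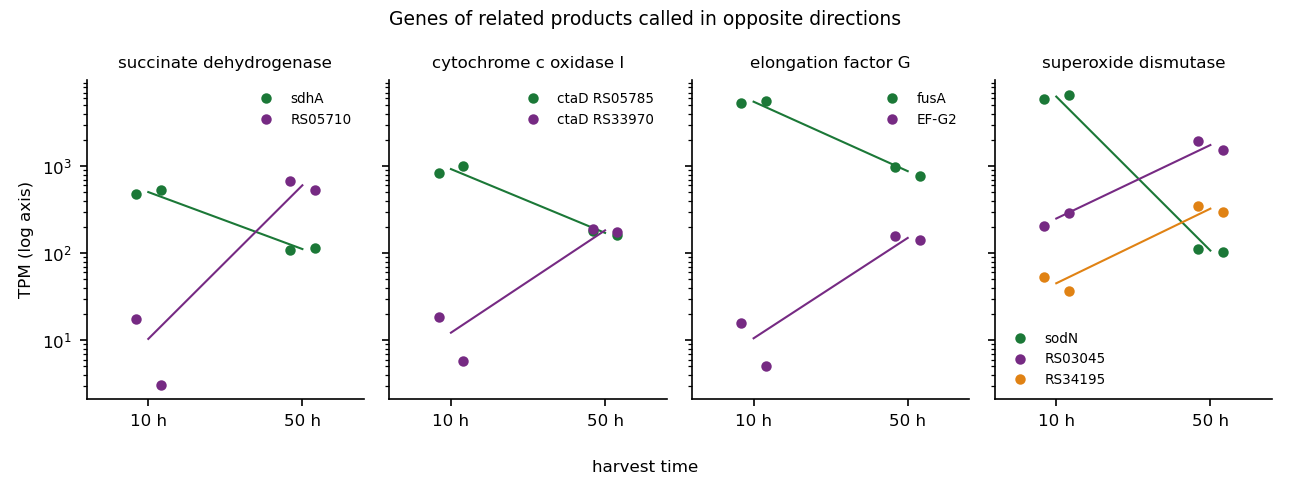
Each panel plots the TPM of genes of related products on a log axis against harvest time, with 1 point per library (n = 2 per time) and a line joining the means. In each panel a gene that fell stands beside 1 or more that rose, such as sdhA with a log2 difference of -2.16 and SACE_RS05710 with 6.10, and the genes were picked after their values were seen.

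Many genes of central carbon metabolism fell. The succinyl-CoA ligase subunits sucD (SACE_RS32090) and sucC (SACE_RS32095), of the tricarboxylic acid cycle, had log2 differences of -3.68 ± 0.16 and -3.65 ± 0.17. The value of sucC went from 2495 ± 275 to 197 ± 9.89 TPM. Of 20 cycle genes 13 were called lower and 2 higher (camera adjusted p = 4.54e-06; adjusted p = 0.59 with an estimated correlation), the 2 being the SACE_RS05710 and SACE_RS05715 genes named above. For the cycle the median log2 difference was -1.76, or -2.94 relative to the all-gene median. In the pentose phosphate pathway, transketolase (tkt, SACE_RS10565) fell from 878 ± 86.6 to 82.1 ± 8.24 TPM (log2 difference -3.40 ± 0.16, adjusted p = 3.66e-08) and its neighbour transaldolase (tal, SACE_RS10560) by 3.26 ± 0.16. Of 24 genes of glycolysis and the pentose phosphate pathway 15 were called lower and 0 higher, with 9 not called (camera adjusted p = 4.44e-12; adjusted p = 0.59 with an estimated correlation). Across it the median log2 difference was -2.08, or -3.26 relative to the all-gene median.

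Some fatty acid oxidation genes rose, and most were not called. An acyl-CoA dehydrogenase (SACE_RS25980), an enzyme of the first step of fatty acid oxidation, rose from 9.92 ± 7.86 to 434 ± 77.3 TPM (log2 difference 5.52 ± 0.35, adjusted p = 3.64e-05). Its standard error was 0.72 in the fit on genes with a mean of at least 100 TPM. Of 69 fatty acid oxidation genes 16 were called higher, 0 lower and 53 neither (camera adjusted p = 0.0184; adjusted p = 0.985 with an estimated correlation). In this set the median log2 difference was 2.15, or 0.98 relative to the all-gene median. The list median fell to 0.22 after quantile normalization and to 0.12 after background subtraction with a pseudocount of 50, and was 1.29 after median-ratio scaling (camera adjusted p = 0.013, 0.00382 and 0.00219). That list's adjusted p was 0.0751 without 50 h replicate 1 and 0.0531 without 50 h replicate 2. A group of 4 nearby genes rose by the next largest log2 differences after the XRE regulator among genes with a described product, a 50 h mean of at least 50 TPM and no overlap between times. They encode an acetoin dehydrogenase acetyltransferase subunit (SACE_RS23065, 7.86 ± 0.31), alpha-ketoacid dehydrogenase subunit beta (SACE_RS23060, 7.72 ± 0.29), a thiamine pyrophosphate-dependent dehydrogenase subunit (SACE_RS23055, 7.67 ± 0.37) and an ATP-NAD kinase (SACE_RS23050, 7.12 ± 0.42). In that order their standard errors were 0.66, 0.69, 1.04 and 1.27 in the fit on genes with a mean of at least 100 TPM. Their values were 9.75 to 13.14 TPM in 10 h replicate 1, near its lowest decile of 11.12 TPM, and 0.31 to 1.21 TPM in replicate 2. Sizes and ranks thus depend on the low end. After background subtraction with a pseudocount of 50 the log2 differences were 4.81, 4.8, 4.42 and 3.96. With a pseudocount of 1 SACE_RS23065 (10.08) passed the XRE regulator (10.05). SACE_RS23065 rose from 5.48 ± 6.04 to 1149 ± 258 TPM (adjusted p = 1.39e-06).

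Many genes of amino acid, nucleotide and cobalamin synthesis fell. Of 92 amino acid synthesis genes 39 were called lower and 0 higher, with 53 not called (camera adjusted p = 1.61e-07; adjusted p = 0.59 with an estimated correlation). Among its genes the median log2 difference was -0.76, or -1.93 relative to the all-gene median. Both methionine synthases were among them, with metE (SACE_RS23015) going from 517 ± 46.4 to 40.7 ± 12.9 TPM (log2 difference -3.67 ± 0.20, adjusted p = 1.06e-07) and metH (SACE_RS18900), the cobalamin-dependent enzyme, from 615 ± 36.3 to 54.8 ± 10.0 TPM (log2 difference -3.48 ± 0.18). Of 30 purine and pyrimidine synthesis genes 24 were called lower and 0 higher (camera adjusted p = 2.38e-14; adjusted p = 0.59 with an estimated correlation). For this group the median log2 difference was -1.53, or -2.71 relative to the all-gene median. Phosphoribosylglycinamide formyltransferase (purN, SACE_RS32075) fell from 862 ± 0.21 to 106 ± 1.33 TPM, and thymidylate synthase (thyX, SACE_RS28285) fell by 2.89 ± 0.18 on the log2 scale. Of 21 cobalamin synthesis genes 13 were called lower and 0 higher (camera adjusted p = 0.00136; adjusted p = 0.877 with an estimated correlation). For that pathway the median log2 difference was -1.36, or -2.54 relative to the all-gene median. The precorrin-8X methylmutase cobH (SACE_RS28545) fell from 268 ± 18.3 to 45.9 ± 8.10 TPM. Among genes with a mean of at least 100 TPM the camera adjusted p was 0.0791 for aminoacyl-tRNA synthetases, translation factors and the tricarboxylic acid cycle, and 0.0852 for cobalamin synthesis. The medians of all 11 lists described so far kept their sign under quantile normalization and median-ratio scaling.

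**Figure D3:**
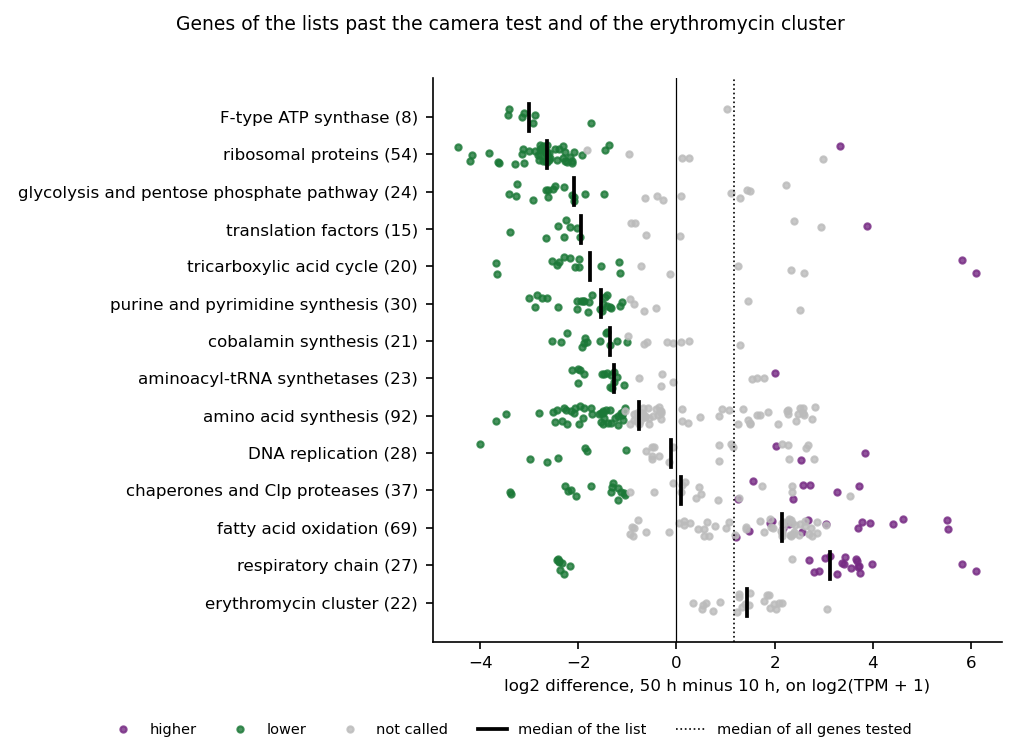
Each point is 1 tested gene, placed by its log2 difference (50 h minus 10 h, horizontal axis) on the lines of the 13 lists past the camera test and of the erythromycin cluster, with the number of genes in brackets. Thick bars are list medians, from -3.01 for ATP synthase to 3.13 for the respiratory chain, the dotted line is the all-gene median of 1.18, and the small positive median of the chaperone list turned negative under quantile normalization and median-ratio scaling.

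Chaperone and DNA replication genes went both ways. The chaperonins groL (SACE_RS02590) and groES (SACE_RS32320), which fold newly made proteins, fell, with log2 differences of -3.39 ± 0.22 and -3.38 ± 0.23. The value of groL went from 4926 ± 899 to 469 ± 79.8 TPM. A small heat shock protein of the Hsp20 family (SACE_RS17740) rose from 9.59 ± 1.19 to 139.7 ± 25.9 TPM (log2 difference 3.72 ± 0.63, adjusted p = 1.85e-08 over all tested genes), a call lost without 50 h replicate 1 (3.54, adjusted p = 0.199). Of 37 chaperone and Clp protease genes 7 were called higher and 15 lower (camera adjusted p = 0.0258, direction down; adjusted p = 0.59 with an estimated correlation). The list median was 0.09 and the mean 0.08, and the median was -0.50 after quantile normalization (adjusted p = 0.647) and -0.89 after median-ratio scaling (0.173). The camera call was also lost after background subtraction with pseudocounts of 1 and 50 (0.322 and 0.366), at a mean of at least 100 TPM (0.0852), without 10 h replicate 2 (0.0531) and without 50 h replicate 2 (0.231). Of 28 DNA replication genes 3, all ATP-dependent DNA ligases, 2 of them chosen after their values were seen, were called higher and 7 lower (camera adjusted p = 0.0452, direction down; adjusted p = 0.877 with an estimated correlation), with a median of -0.12 and a mean of 0.26. Its camera call was lost after quantile normalization (0.849), after median-ratio scaling (0.173), after background subtraction with pseudocounts of 1 and 50 (0.284 and 0.246), at a mean of at least 100 TPM (0.313), and without 10 h replicate 1 (0.0646), 10 h replicate 2 (0.0687) or 50 h replicate 2 (0.0637). The ligase SACE_RS17215, with a log2 difference of 3.84, was not called without 10 h replicate 2 (2.69), 50 h replicate 1 (3.92) or 50 h replicate 2 (3.75). Nor was SACE_RS09120 (log2 differences 1.53, 2.12 and 1.93). The calls of SACE_RS09120 and the other ligase, SACE_RS09060, were lost after median-ratio scaling (0.107 and 0.0627). A single-stranded DNA-binding protein gene (SACE_RS35470) fell from 1957 ± 207 to 121 ± 10.4 TPM (log2 difference -4.00 ± 0.16, adjusted p = 2.15e-08).

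The erythromycin cluster had no gene called between the times, though the tag between SACE_0720 and SACE_0722 had no matched gene and could not be tested. Its 22 measured genes, which include KR domain-containing, tailoring and sugar enzymes, the self-resistance methyltransferase and a transposase, had 0 called at all, 0 when adjusted over the list alone and 1 at an unadjusted p under 0.05 in the limma fit (camera adjusted p = 0.546). The median of the cluster genes was 23.02 and 4.66 TPM in 10 h replicates 1 and 2 and 23.36 and 50.99 TPM in 50 h replicates 1 and 2. Their median percentile among all genes of the library was 41.6, 32.8, 34.3 and 44.3 in that order. The resistance gene ermE (SACE_RS03595), which methylates 23S ribosomal RNA, was 62.2 ± 8.79 TPM at 10 h and 78.5 ± 8.24 TPM at 50 h (log2 difference 0.33 ± 0.32, adjusted p = 0.399 over all tested genes). The hydroxylase gene eryF (SACE_RS03580) was 30.5 ± 7.06 and 45.2 ± 18.1 TPM (log2 difference 0.52 ± 0.65). The desosaminyl transferase gene eryCIII (SACE_RS03560) was 12.5 ± 11.9 and 31.2 ± 18.6 TPM (log2 difference 1.49 ± 1.48). The median log2 difference of the cluster was 1.44, or 0.27 relative to the all-gene median, and it was 0.04 after quantile normalization and 0.51 after median-ratio scaling. Leaving out 1 library at a time moved it between 0.52 and 2.31. The erythromycin esterase gene (SACE_RS03490), listed at 33.8 and 0 TPM at 10 h and at 31.7 and 74.4 TPM at 50 h, was called higher after median-ratio scaling (adjusted p = 0.00264) and without 10 h replicate 1 (0.0107). With crossed replicate numbers as a block 14 of the 22 genes were called higher, the esterase gene among them (adjusted p = 6.29e-05). That block pairs the libraries with the lower lowest decile of each time (0.63 and 15.85 TPM), and those with the higher (11.12 and 38.26 TPM). It called 3038 genes higher in all, against 789 without it, so the 14 calls are not particular to the cluster. After background subtraction the mycarosyltransferase gene (SACE_RS03525) was called lower (log2 difference -2.85, adjusted p = 0.0256). Its 50 h values of 15.79 and 36.33 TPM lay below the subtracted deciles of 15.85 and 38.26 TPM and were set to 0, so that call follows from the subtraction.

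Of 9 regulators tied to erythromycin production, 3 fell and 0 rose (camera adjusted p = 0.122). These were a hypothetical protein (SACE_RS26835, log2 difference -1.84 ± 0.27), a DNA-binding response regulator (SACE_RS34275, -1.74 ± 0.16), from 601 ± 26.7 to 179 ± 16.9 TPM, and a TetR family regulator (SACE_RS33965, -1.54 ± 0.25). The developmental regulator bldD (SACE_RS10165) was 1194 ± 112 TPM at 10 h and 626 ± 108 TPM at 50 h (log2 difference -0.94 ± 0.18), short of the minimum difference, and was called lower without 10 h replicate 1 (-1.03, adjusted p = 0.000526) or 50 h replicate 1 (-1.11, 4.31e-07). Of the TetR family regulators on the list SACE_RS16705 was called higher after background subtraction (1.24, 0.0146) and with crossed replicate numbers (1.56, 0.00175), SACE_RS19340 higher with crossed numbers (1.23, 0.00987), and SACE_RS27580 lower after background subtraction (-1.01, 0.00187). Of 14 genes supplying methylmalonyl-CoA and malonyl-CoA, the building blocks of the polyketide, 1 was called higher and 2 lower (camera adjusted p = 0.876). The 2 were a propionyl-CoA carboxylase beta subunit (SACE_RS16480), from 254 ± 29.8 to 51.6 ± 9.47 TPM, and an acetyl-CoA carboxylase carrier subunit (SACE_RS30895), from 459 ± 79.3 to 131 ± 6.56 TPM. The 1 called higher was a methylmalonyl-CoA mutase gene (SACE_RS27025, log2 difference 1.01 ± 0.34), lost without 10 h replicate 2 (0.85) and without 50 h replicate 2 (0.91) and at 0.03 after median-ratio scaling. Of 29 genes on the list of other polyketide, peptide and terpene synthases 2 were called higher and 1, an acyl-CoA thioesterase (SACE_RS27405) that is none of these, lower (camera adjusted p = 0.477), led by a type III polyketide synthase (SACE_RS06060) that rose from 12.8 ± 12.6 to 502 ± 78.2 TPM. The other called higher, a peptide synthetase (SACE_RS14730), was not called after median-ratio scaling (0.49, adjusted p = 0.523).

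Nitrogen genes also divided. The nitrite reductase small subunit nirD (SACE_RS18435) rose from 11.5 ± 12.4 to 324 ± 42.4 TPM (log2 difference 5.19 ± 0.42, adjusted p = 0.00198). Its standard error was 1.19 in the fit on genes with a mean of at least 100 TPM. A urease gamma subunit (SACE_RS12325) had a log2 difference of 4.74, and its call was lost without 50 h replicate 1 (4.72) or 50 h replicate 2 (4.75). The 4 called lower were the gltB and gltD genes of 2 glutamate synthases, of which gltB (SACE_RS19400, chosen after its values were seen) fell from 333 ± 15.9 to 29.8 ± 15.0 TPM. Of 37 genes 8 were called higher and 4 lower (camera adjusted p = 0.925), with a median of 2.58 and a mean of 1.5 against a camera direction of down, which turned to up after quantile normalization (median 0.67, adjusted p = 0.0232), median-ratio scaling (0.0657), background subtraction with pseudocounts of 1 and 50 (0.104 and 0.0929) and without 10 h replicate 1 (0.67) or 10 h replicate 2 (0.771). Oxidative stress genes had 8 of 38 called higher and 8 lower (camera adjusted p = 0.401). Against the fall of sodN, superoxide dismutase genes SACE_RS34195 and SACE_RS03045 had log2 differences of 2.84 ± 0.22 and 2.81 ± 0.17 (adjusted p = 5.98e-07 and 6.33e-07). Both calls were lost after median-ratio scaling (log2 differences 1.85 and 1.82, adjusted p = 0.0609 and 0.207). Fatty acid synthesis had 2 of 26 called higher and 5 lower (camera adjusted p = 0.122), and an acyl carrier protein (SACE_RS07475) fell from 3482 ± 326 to 123 ± 26.0 TPM. The other 4 called lower were a beta-ketoacyl carrier protein synthase and, chosen after their values were seen, an S-malonyltransferase, fabI and a fabG. The 2 called higher were another fabG (SACE_RS25985, 4.38 ± 0.26), from 19.8 ± 8.20 to 416 ± 58.4 TPM, and a 3-oxoacyl carrier protein synthase (SACE_RS16800, 3.84 ± 1.19). The call of SACE_RS16800 was lost without 50 h replicate 1 (3.99) or 50 h replicate 2 (3.68). Development and sporulation had 3 of 22 called higher and 1 lower (camera adjusted p = 0.0624, and 0.032 without 50 h replicate 1 or 0.0476 without 50 h replicate 2). That list also passed after quantile normalization (0.0353), after background subtraction with pseudocounts of 1 and 50 (0.0307 and 0.0373) and among genes with a mean of at least 100 TPM (0.00895). It did not after median-ratio scaling (0.523), without 10 h replicate 1 (0.257) or without 10 h replicate 2 (0.332). Its WhiB family regulator SACE_RS32310 rose from 377 ± 5.58 to 7883 ± 1167 TPM (log2 difference 4.37 ± 0.24, adjusted p = 3.69e-08). The WhiB gene SACE_RS31085 also rose (3.90 ± 0.20), and the WhiB gene SACE_RS01545 was the gene called lower (-1.54 ± 0.23, adjusted p = 0.000389). The calls of SACE_RS31085 and of whiG (SACE_RS28965) were lost after median-ratio scaling (2.90 and 0.99, adjusted p = 0.0681 and 0.17).

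The remaining lists did not pass the camera test. Members named in the next sentences without a value were in part chosen after their values were seen. Iron uptake had 2 of 24 called higher, a siderophore-interacting and a siderophore-binding protein, and 7 lower (adjusted p = 0.299, and 0.0232 after quantile normalization, 0.00367 after median-ratio scaling, and 0.0284 and 0.0159 after background subtraction with pseudocounts of 1 and 50). Both calls higher were lost after median-ratio scaling (SACE_RS19785 from 1.63 to 0.64, adjusted p = 0.469, and SACE_RS14725 from 1.44 to 0.45, 0.624). Cell division and peptidoglycan synthesis had 5 of 44 called higher, an ftsK, a parA, a sepF, an ftsZ and a penicillin-binding protein gene, and 15 lower (0.165, and 0.0206 after median-ratio scaling), with ftsE (SACE_RS05410) falling by 3.44 ± 0.17 on the log2 scale. All 5 calls higher were lost after median-ratio scaling (log2 differences 0.20 to 1.39, adjusted p from 0.233 to 0.886), and that of ftsK also without 10 h replicate 2 (0.0864), 50 h replicate 1 (0.134) or 50 h replicate 2 (0.0923). Carbohydrate ABC transporters had 8 of 47 called higher and 0 lower (0.165, and 0.000125 after median-ratio scaling and 0.0405 and 0.0278 after background subtraction with pseudocounts of 1 and 50). Secreted hydrolases had 9 of 73 called higher and 6 lower (0.781), and a glycoside hydrolase (SACE_RS08325) fell from 3179.8 ± 424 to 62.0 ± 13.0 TPM. Branched-chain amino acid degradation had 2 of 8 higher, mmsA and mmsB, and 1 lower, panB (0.224), and the mmsB call (SACE_RS07145) was lost after median-ratio scaling (1.57, adjusted p = 0.11). Phosphate uptake had 1 of 21 higher and 3 lower (0.925), the first an ATPase of a sugar phosphate transporter and the others pstB, pstS and a polyphosphate kinase. Sigma and anti-sigma factors had 6 of 48 higher and 5 lower (0.925), the latter sigM, shbA, rsrA and a pair of SigE family genes. The shbA call (SACE_RS32295) was lost without 50 h replicate 2 (adjusted p = 0.0551), and it and the rsrA call (SACE_RS30900) after median-ratio scaling (0.131 and 0.13) and quantile normalization (log2 differences -0.81 and -0.49), where pstS (SACE_RS34265) was also not called (-0.83). The transporter ATPase (SACE_RS20180), with a log2 difference of 4.16, was not called without 50 h replicate 1 (4.17) or 50 h replicate 2 (4.14). Nor was the kinase (SACE_RS29460) without 10 h replicate 1 (log2 difference -0.99), 10 h replicate 2 (-1.08) or 50 h replicate 1 (-0.80). TetR family regulators had 8 of 139 higher and 13 lower (0.925), which became 6 and 6 of 118 with members of other function left out. Transposases and integrases had 4 of 106 higher and 3 lower (0.373), glycogen and trehalose metabolism 0 of 4 higher and 2 lower (0.607), and amino acid and peptide transporters 2 of 42 higher and 4 lower (0.925). Adjusted over the list alone the total called was unchanged for every list except ribosomal proteins (50 for 49), TetR regulators (20 for 21), transposases (3 for 7) and amino acid transporters (4 for 6). Camera gave the direction down, relative to all other genes, with a median and mean above 0, for the supply, fatty acid synthesis, phosphate, chaperone, nitrogen, oxidative stress, cell division, sigma factor and glycogen lists. Relative to the all-gene median the list medians were -0.12 for supply, -1.08 for chaperones, -0.52 for oxidative stress, -0.92 for cell division, -0.22 for sigma factors and -0.83 for glycogen. They were 0.12 for fatty acid synthesis, 0.27 for phosphate and 1.41 for nitrogen, where why camera pointed down was not tested.

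Several of these counts were not stable. Of the calls higher, those of nitrogen genes kept were 2 of 8 without 50 h replicate 1, 3 without 50 h replicate 2 and 4 with the replicate number as a block. In the same order carbohydrate transporters kept 2, 2 and 4 of 8, and chaperones 3, 4 and 4 of 7. Secreted hydrolases kept 5 of 9 without 50 h replicate 1. Sigma and anti-sigma factors kept 3 of 6 without 10 h replicate 2, without 50 h replicate 1 and with the block. After median-ratio scaling fatty acid oxidation kept 9 of 16 calls higher, oxidative stress 2 of 8, TetR regulators 1 of 8, sigma factors 2 of 6, transposases 2 of 4 and development and sporulation 1 of 3. After background subtraction with a pseudocount of 50 sigma factors kept 1 of 6, TetR regulators 4 of 8 and transposases 1 of 4. Without 10 h replicate 2 transposases kept 1 of 4 calls higher and 0 of 3 lower. Fatty acid synthesis kept 1 of 2 calls higher without either 50 h library, and amino acid and peptide transporters did so there, without 10 h replicate 2 and after median-ratio scaling. Of the calls lower, aminoacyl-tRNA synthetases kept 7 of 15 after quantile normalization, and chaperones 9 of 15 after it and after median-ratio scaling. With an estimated correlation 0 lists passed in any alternative, and the adjusted p was 0.877 for development and sporulation and 0.985 for iron uptake and carbohydrate transporters with TPM as deposited.

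The most abundant stationary-phase transcripts encoded proteins of unknown function. The hypothetical protein gene SACE_RS06835 rose from 790.2 ± 50.4 to 52609.7 ± 1912 TPM, SACE_RS27550 from 269.8 ± 9.02 to 48448 ± 3742 TPM, SACE_RS34860 from 503 ± 119 to 46371 ± 3878 TPM and SACE_RS01110 from 891 ± 52.3 to 41842 ± 4367 TPM. Their log2 differences were 6.06 ± 0.49, 7.48 ± 0.35, 6.54 ± 0.41 and 5.55 ± 0.47, and the largest adjusted p among the 4 was 3.46e-08. Without 10 h replicate 2 the fit over all genes no longer called them, with log2 differences of 5.99, 7.45, 6.78 and 5.61 and adjusted p of 0.733, 0.0871, 0.241 and 0.622. The 4 most abundant genes of each library held 19.9% and 17.9% of all TPM at 50 h and 3.7% and 4.3% at 10 h.

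Some of the 1790 called genes lay side by side on the chromosome. The ribosomal protein region formed the longest run, 19 neighbouring genes called lower with a median log2 difference of -2.66, and the NADH-quinone oxidoreductase region gave 15 neighbours called higher with a median of 3.41. Other runs called lower held a fructose phosphotransferase system (8 genes, median -3.64), methionine and adenosylhomocysteine enzymes (7 genes, -3.78) and a glycine betaine transporter (7 genes, -2.66). Other runs called higher held nitrate and nitrite genes (9 genes, 4.28), acyl-CoA dehydrogenases (7 genes, 4.78) and a block of mostly hypothetical proteins around SACE_RS06835 (7 genes, 5.74). In the order of 6759 tested genes, 38 runs of at least 6 genes were called 1 way, 11 higher and 27 lower, with 291 genes in them. Shuffled orders gave 0.072 runs on average and 2 at most over 10000 shuffles (permutation p = 1e-04, the smallest they can give), a description across genes, which are not replicates.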

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

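The filter at 100 TPM, the crossed numbers, the 2 background subtractions and the cleaned lists were tests chosen only after the results were seen. With pseudocounts of 0.1 and 5, no filter, a 10 TPM filter, quantile normalization, median-ratio scaling and no minimum difference the number of called genes lay between 1739 and 2396, against 1790. Without the intensity trend 0 genes were called, with 0 higher, 0 lower and 0 runs, where the prior had 1.56 degrees of freedom; 2006 genes had an unadjusted p under 0.05 and 16 lists passed camera. Background subtraction gave 2978 genes, 1314 higher and 1664 lower, 85 runs and 1 erythromycin gene, the mycarosyltransferase (SACE_RS03525), which turned to -2.85 because its 50 h values were set to 0. With a pseudocount of 50 the subtraction gave 1404 genes with 515 higher. Among genes with a mean of at least 100 TPM 1096 were called, 315 higher, and 8 lists passed. The cleaned lists gave 13 lists, as before. Median-ratio scaling called 1 erythromycin gene. The camera direction of the nitrogen list turned under quantile normalization (median 0.67, adjusted p = 0.0232), median-ratio scaling, both background subtractions and without either 10 h library. That of the respiratory chain list turned without 50 h replicate 1, while its median was 3.05 there and 2.75 to 3.75 over the libraries left out. Leaving out 1 library gave 1377 to 2067 genes, 488 to 1120 higher, 869 to 1131 lower, 27 to 41 runs, 0 to 1 erythromycin genes and 10 to 12 lists, and S14 type Z (SACE_RS32850) turned to -3.17, against 9.81 without 10 h replicate 1. Other causes were not tested. Of 198 called genes among the 226 allowed or chosen, calls kept were 181 under median-ratio scaling, 193 under quantile normalization, 194 after background subtraction, 162 of 165 at 100 TPM, and 196, 181, 171 and 177 without 10 h replicates 1 and 2 and 50 h replicates 1 and 2. The labels do not say what a replicate number stands for, so whether same-numbered samples share anything is unknown. The replicate block gave 1478 genes, 538 higher and 940 lower, 0 erythromycin genes, 32 runs and 13 lists. Deviations of same-numbered samples correlated at -0.25 over 6960 genes and 0.54 over the 1578 at 100 TPM or more. Crossed numbers as a replicate block gave 4067 genes, 3038 higher, 1029 lower, 14 erythromycin genes and 162 runs. Crossing pairs libraries by their lowest decile, lower with lower and higher with higher, so part of that difference goes into the block. Depth is unknown, and low genes are limited by each library's lowest values.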

Other observations

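The tests of an even background, of a scale factor, of growth phase and of the background of the erythromycin genes were chosen only after the results were seen.

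Several neighbouring gene groups mostly outside the lists above changed together. A run of 6 genes with an acetate symporter and a dynein regulation LC7 protein (SACE_RS30445, log2 difference 4.27 ± 0.20) was called higher, with a median of 2.92. Runs of 8 and 7 genes that also hold LC7, DUF742 and ATP-binding proteins were called lower, with medians of -2.75 and -2.63. A run of 9 hydrogenase assembly genes was called higher, with a median of 3.02. Its gene hypF (SACE_RS14925, 4.49 ± 0.80) was no longer called without 50 h replicate 1 (log2 difference 4.48) or 50 h replicate 2 (4.5). A pair of WXG100 proteins, targets of type VII secretion, fell, SACE_RS32630 from 2899 ± 409.8 to 140.4 ± 9.23 TPM and SACE_RS32635 from 2715 ± 247 to 139 ± 20.9 TPM. The thiamine synthesis gene thiC (SACE_RS02510) fell from 748 ± 86.3 to 40.2 ± 17.9 TPM (log2 difference -4.25 ± 0.18).

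The low values differed between libraries, and the lowest decile differed 17.7-fold between the 10 h libraries and 2.41-fold between the 50 h libraries, which argues against growth phase as the whole cause. A single scale factor per library was argued against, since the ratio of the 10 h libraries was 6.12 for low genes and 0.89 for abundant ones, 6.9 times apart. The 765 genes under 1 TPM in 10 h replicate 2 had a median of 11.3 TPM (quartiles 10.0 and 12.8) in 10 h replicate 1, and in 2 of the 3 other libraries they stood higher near the replication origin than far from it, beyond the bootstrap interval, so a background of equal level in every gene is argued against. In 10 h replicate 1 the ratio was 1.89 between the 31 nearest and the 336 farthest genes (95% interval 1.75 to 2.02), which would be consistent with DNA of replicating chromosomes in that library, against 1.15 (1.0 to 1.26) and 1.1 (1.04 to 1.18) at 50 h. Low-level transcription that follows gene dosage was not tested and stays open.

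The median of the erythromycin cluster genes lay below that of all genes in every library, with 5 to 9 of the 22 above it. In each 50 h library 2 of the 22 genes lay above the 95th percentile of 21 comparison genes, and 5 did in 10 h replicate 1. The comparison genes were under 1 TPM in 10 h replicate 2. They lay at a like distance from the replication origin, on either chromosome arm, so not necessarily near the cluster. The cluster median exceeded that of the comparison genes by 2.9 TPM in 10 h replicate 1 and by 2.5 and 3.6 TPM in the 50 h libraries. The 50 h values may thus be largely background, in which case a change in the cluster would be hidden. The library 10 h replicate 2, used to choose the comparison genes, could not be compared in this way. There the cluster genes ranged from 0 to 55.98 TPM with a median of 4.66 TPM. Over all genes of that library the median was 14.63 TPM and the lowest decile 0.63 TPM. Low transcription of the cluster in this medium and at these times, the biological explanation the design allows, stays open and untested.

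Ribosomal protein genes were lower at 50 h, where 10 genes took 27.6% and 24.1% of all TPM. If dilution by those 10 genes were the whole cause, removing them and rescaling would bring the list median above -1. The median went from -2.63 to -2.21, with an interquartile range over the list of 0.56. The size of that shift is set by the shares of the 10 genes, so the removal was not an independent test. Shares of 27.6% and 24.1% are too small for dilution by these genes alone to give a median of -2.63. Background also does not account for the sign, since the median was -2.44 after background subtraction. Growth phase, which the design confounds with harvest time, may contribute and stays open as a hypothesis, since total RNA per cell was not measured here.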
